A study of Mus musculus with 4 samples.

How the data were processed

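Gastrocnemius muscle, a calf muscle of mostly fast fibres, was taken from control mice (Con) and from mice whose skeletal muscle lacks CaMKIIγ and CaMKIIδ (KO). CaMKII is a kinase that calcium and calmodulin activate. Per the labels, total RNA was extracted with ISOGEN II reagent and RNeasy Mini columns and sequenced by BRB-seq, a method that counts the 3′ ends of polyadenylated transcripts. Each RNA was reverse transcribed with an oligo-dT primer that carries a barcode of 9 nt and a unique molecular identifier (UMI) of 10 nt. The replicates were then mixed, and the mix was amplified by PCR. The cDNA insert was read over 81 nt. There were 4 groups of 4 barcoded libraries, 16 libraries in all: Con and KO before training, and Con and KO after 4 weeks of endurance training. Each of the 4 pools holds 1 group, so a difference between pools and a difference between groups cannot be told apart in these data. Whether the 4 replicates of a group are separate animals, and the ages of the mice, is not given in the sources used here.

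The deposited table holds raw read or UMI counts (unit: counts) per gene and library, with no normalization by the authors. The values are whole numbers. Per the labels, the authors used UMI-tools, Trim Galore 0.6.10, HISAT2 2.2.1 and featureCounts 2.0.6 with genome build GRCm38. Whether reads with the same UMI were collapsed, the strand setting and the annotation release are not given in the sources used here. A deposited list of barcodes gives the pool of each library and no measurement, and no value here uses it. It does not say whether the pools were amplified apart. The table lists 21094 genes, each with at least 1 count. Total counts ranged from 986046 to 1976537 per library, so 3 counts in a library corresponded to between 1.54 and 2.91 CPM, counts scaled to a library total of 1e6. Limits set by counts cover counting error alone.

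Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr by group, which left 7393 genes holding at least 98.4% of the counts of each library. Library sizes were scaled by the trimmed mean of M values (TMM). A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 16 libraries, with no covariate. The common dispersion was 0.0106, a biological coefficient of variation of 10.3%. The 6 comparisons were KO against Con before training, KO against Con after training, after against before training in Con, the same in KO, the difference between the training effects in KO and Con, and KO against Con averaged over both training states. Tests were two-sided F tests, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison. Genes with an adjusted p under 0.05 were called, and called genes are said to have risen, fallen or changed. Log2 fold changes are given with their standard error (SE), and levels as mean CPM with the SD over 4 libraries.

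Before the data were examined, 32 gene lists were fixed for fibre types, energy metabolism, calcium handling, signalling, stress, matrix, secreted factors and the other cell types that a piece of muscle could hold. Of these, 30 had enough measured genes to be tested. Some genes are in more than 1 list, so the list calls are not independent. The list of excitation-contraction coupling shares Atp2a2, Casq2 and Sln with the slow-fibre list, and Atp2a1 and Casq1 with the fast-fibre list. The granulocyte list had 0 measured genes and the adipocyte list 1. For 1 listed symbol that 2 genes of the table share, the gene with more counts was taken. Each list was compared with the other genes by camera (limma 3.58.1) with a preset correlation between genes of 0.01, and p-values were adjusted over the 30 lists within a comparison. Camera was also run with a correlation estimated for each list. Members were also called with p-values adjusted over the list alone. Another test, fry, asked whether the genes of a list move on balance in 1 direction, without comparing them with other genes.

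Named genes followed a rule fixed at the same time. The rule took the 4 CaMKII genes, then the 10 largest called changes in each direction with a mean of at least 10 CPM and no overlap between the groups, then up to 4 called members of each list. Where fewer than 3 genes passed in a direction, it took the 3 with the smallest p. Unnamed gene models were counted but not named, and exceptions are stated where they occur. Of the genes the rule takes, 3 are not reported here. Positions are 1-based and come from the GENCODE M21 annotation of GRCm38. Pseudogenes were matched to coding genes with blastn 2.17.0.

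Counts of called genes were recomputed under alternatives: DESeq2 1.42.0, another scaling (RLE), no filter on low counts, mitochondrially encoded genes left out, limma voom with library weights, the replicate number as a block, the 2 compared groups alone, and each of the 16 libraries left out in turn. Calls of named genes were recomputed under all of these but the 2 groups alone. List calls were recomputed with RLE, no filter, the replicate block and each library left out, beside the estimated correlation and fry. After the data had been seen, 3 more were added: pseudogenes left out, trends with transcript length and GC content removed, and counts of pseudogene copies added to their coding gene. The copies had at least 95% identity over at least 50% of their length, and 46 were added. The closing section gives the effects.

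The method was tested on simulated data with the depth and spread of these libraries. Of 100 genes changed 1.5-fold, edgeR called 19 before training, and of 100 changed 2-fold it called 76, with 4 false calls. For the difference between training effects, it called 6 and 38 of 100, with 1 false call. A list of 21 genes lowered 1.25-fold was called by camera in both simulations, with an adjusted p of 2.28e-07 and of 0.00534, and no other list was called. Genes were simulated independently of one another, so the simulations do not test how correlation between genes affects the list calls.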

Results

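The data are counts of transcript 3′ ends in 16 libraries of mouse gastrocnemius, 4 in each of 4 groups. The groups are Con before training (Con-pre), KO before training (KO-pre), Con after 4 weeks of endurance training (Con-post) and KO after the same training (KO-post). A library is named by its group and replicate, as in KO-pre 1. The libraries held 1065097 to 1746823 counts in Con-pre, 986046 to 1550974 in KO-pre, 1081330 to 1331795 in Con-post and 1213840 to 1976537 in KO-post. Of 21094 genes in the table, 7393 passed the filter on low counts. Mitochondrially encoded transcripts took 27.7% ± 1.18 of the counts in Con-pre, 25.0% ± 1.62 in KO-pre, 28.3% ± 1.85 in Con-post and 26.2% ± 1.65 in KO-post (SD, n = 4 each). The first principal component of the 500 most variable genes held 26.1% of their variance, and its scores were negative in all 8 Con libraries and positive in all 8 KO libraries. The second held 18.1%, with positive scores before training and negative scores after it. The chi-square per degree of freedom between pairs of replicates ranged from 2.03 to 8.15, against 1 for counting error alone. Nothing in the labels says that the replicates of a group are separate animals, so the p-values measure the spread between these libraries, which may be technical. The annotation gives some named genes exon bases that another gene shares, which leaves their counts less certain. The shares were 73.5% in Mt2, 23.2% in Ccn2, 19.6% in Fabp3, 19.1% in Gadd45a, 19.0% in Hspa1a and 12.9% in Ostn. They were 10.7% in Pfkm, 8.0% in Casq1, 6.71% in Exoc7, 6.46% in mt-Atp6 and 5.6% in Acsl3, and other large shares are given beside the gene.

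Transcript counts of both targeted genes were lower in all 8 KO libraries than in any Con library. Camk2g (ENSMUSG00000021820, chromosome 14, 20734875 to 20794088, GRCm38) lay between 121 and 148 CPM in the Con libraries and between 23.8 and 31.1 CPM in the KO libraries. Its mean fell from 138 ± 10.4 CPM in Con-pre to 27.7 ± 3.15 CPM in KO-pre, and from 135 ± 11.4 CPM in Con-post to 25.5 ± 0.871 CPM in KO-post (SD, n = 4 each). The log2 fold changes were -2.32 ± 0.116 (SE; adjusted p = 5.11e-14) before and -2.40 ± 0.113 (adjusted p = 8.4e-15) after training. Camk2d (ENSMUSG00000053819, chromosome 3, 126596302 to 126846326) lay between 31.0 and 55.3 CPM in Con and between 7.17 and 24.1 CPM in KO. It fell by 1.10 on the log2 scale (SE 0.222, adjusted p = 0.00314) before and by 1.80 (SE 0.222, adjusted p = 5.08e-06) after training. Camk2b (ENSMUSG00000057897, chromosome 11, 5969644 to 6066362), which encodes the β form of the kinase, was not targeted and rose in KO. Its level went from 103 ± 5.25 to 147 ± 11.3 CPM before training and from 96.2 ± 5.06 to 164 ± 13.8 CPM after it (SD, n = 4), log2 changes of 0.52 (adjusted p = 0.000834) and 0.77 (adjusted p = 2.62e-06). Camk2a (ENSMUSG00000024617, chromosome 18, 60925618 to 60988152), the gene of the α form, had 235 ± 12.4, 208 ± 10.4, 222 ± 15.9 and 190 ± 26.9 CPM in Con-pre, KO-pre, Con-post and KO-post. Its differences did not pass the test before (adjusted p = 0.389) or after training (adjusted p = 0.204). None of the 4 genes was called for training in either genotype, with edgeR adjusted p-values between 0.33 and 0.948. None shares exon bases with another gene. The deleted exons are not given in the sources used here and the counts come from transcript 3′ ends, so these values show a lower transcript level and not the deletion itself.

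**Figure D1:**
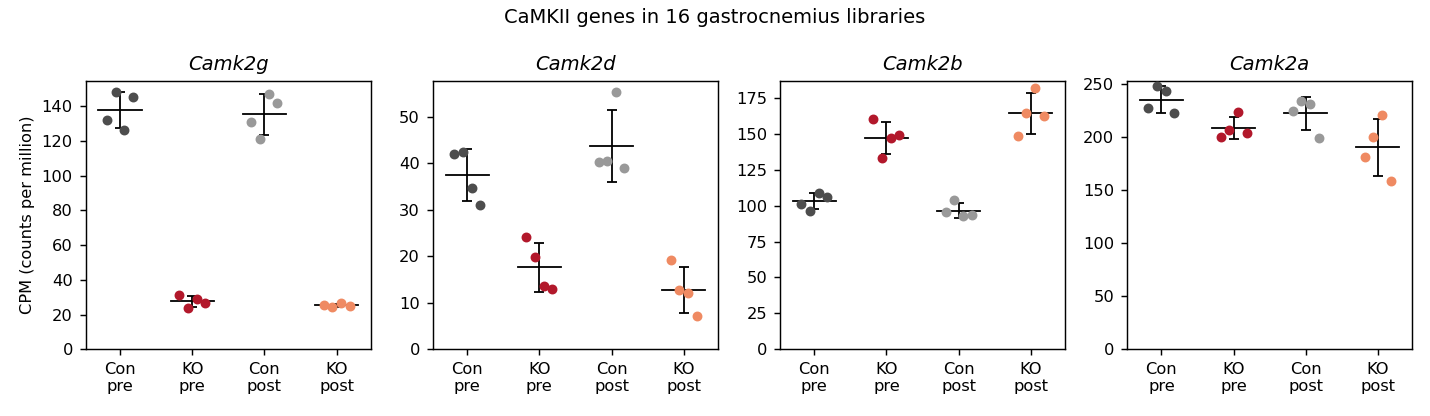
Levels (CPM) of the 4 CaMKII genes in each of 16 libraries, by group, with the mean as a line and the SD as an error bar (n = 4). Camk2g and Camk2d are lower in every KO library than in any Con library, and Camk2b is higher in KO.

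KO against Con before training asks which transcripts differ in muscle without CaMKIIγ and CaMKIIδ at rest. As lists, genes of glycolysis and nuclear genes of the respiratory chain were lower in KO and slow-fibre genes higher, with 13 of 22, 36 of 77 and 8 of 14 members called. The slow-fibre call was lost with an estimated correlation. Among 22 measured genes of glycolysis and glycogen use, 13 fell and 9 were not called (16 fell when adjusted over the list alone). Their median log2 change was -0.42 (camera adjusted p = 6.53e-26, and adjusted p = 0.000282 with an estimated correlation). Ldha, lactate dehydrogenase A, fell from 2820 ± 65.9 to 1600 ± 63.4 CPM (SD, n = 4; log2 -0.82, SE 0.0733, adjusted p = 1.87e-08). Tpi1, triosephosphate isomerase, fell by 0.81 on the log2 scale, Eno3, the muscle enolase, by 0.75, and Pfkm, the muscle phosphofructokinase, by 0.55. Fbp2, the fructose bisphosphatase of muscle, fell from 37.4 ± 13 to 13.3 ± 2 CPM (log2 -1.46, adjusted p = 0.000291). Of 77 nuclear genes of the respiratory chain and ATP synthase, 36 fell and 41 were not called (65 fell when adjusted over the list alone), and 76 had a value below 0. The median was -0.28 (camera adjusted p = 5.81e-41, and adjusted p = 0.0191 with an estimated correlation). Cox7a1, the muscle form of a cytochrome c oxidase subunit, fell from 237 ± 23.7 to 150 ± 14.7 CPM (log2 -0.66, adjusted p = 4.41e-05). Atp5e and Atp5j2 of ATP synthase and Uqcr10 of complex III fell by 0.47, 0.48 and 0.49. Of 10 mitochondrially encoded genes of the chain, 6 fell (6 also over the list alone), with a median of -0.32 (camera adjusted p = 2.65e-07, and adjusted p = 0.196 with an estimated correlation). They include mt-Nd1 of complex I, at -0.41 (SE 0.07, adjusted p = 0.000458), and mt-Cytb of complex III, at -0.35 (SE 0.0713, adjusted p = 0.0036). Idh3a, isocitrate dehydrogenase, was the called gene among 17 of the tricarboxylic acid cycle, with a fall from 571 ± 30.7 to 425 ± 24.6 CPM (3 fell when adjusted over the list alone). The median of that list was -0.14 (camera adjusted p = 0.00594, and adjusted p = 0.504 with an estimated correlation), and its call was lost without KO-pre 1 (adjusted p = 0.072).

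Of 14 measured slow-fibre genes, 8 rose in KO muscle before training and 6 were not called (8 also over the list alone), with a median log2 change of 0.48 (camera adjusted p = 2.07e-10, and adjusted p = 0.0603 with an estimated correlation). Myl2, the slow regulatory myosin light chain, rose from 228 ± 33.8 to 403 ± 73.2 CPM (SD, n = 4; log2 0.83, SE 0.112, adjusted p = 2.5e-05). The slow troponins Tnnt1 and Tnni1 rose by 0.76 and 0.82, and Tpm3, slow tropomyosin, by 0.65. Among 18 fast-fibre genes 1 rose and 4 fell (the same counts over the list alone), and the list was not called (median 0.02, mean 0.01, test direction lower, camera adjusted p = 0.365). Myl1, the fast essential light chain, fell from 15500 ± 934 to 9790 ± 553 CPM (log2 -0.66, SE 0.0711, adjusted p = 4.66e-07). Mylk2, the myosin light chain kinase of skeletal muscle, fell by 0.56, and Myoz1, a Z-disc protein of fast fibres, by 0.35. The fast-fibre gene that rose is Tnnc2, from 8.57 ± 5.21 to 26.9 ± 8.55 CPM, but 74.0% of its exon bases are shared with Ube2c, which makes its counts uncertain. Among 20 genes of excitation-contraction coupling 3 rose (5 over the list alone), with a median of 0.05 (camera adjusted p = 0.0362, and adjusted p = 0.504 with an estimated correlation). Atp2a2, the slow-fibre calcium pump, rose from 190 ± 25.8 to 272 ± 36.2 CPM (log2 0.52, adjusted p = 0.0036), and Ryr1, the calcium release channel, rose from 1490 ± 49 to 1880 ± 105 CPM (log2 0.33, adjusted p = 0.00585). The Ryr1 call was lost with trends of length and GC content removed (adjusted p = 0.0703, the highest of its alternatives). The coupling list lost its call without Con-pre 2 (adjusted p = 0.0516), Con-pre 4 (0.058), KO-pre 1 (0.072) or KO-pre 2 (0.13), and with trends of length and GC content removed (0.0643). Of 18 genes of atrophy and proteolysis 3 rose (6 over the list alone), with a median of 0.35 (camera adjusted p = 0.000294, and adjusted p = 0.47 with an estimated correlation). Ctsl, a lysosomal protease, rose from 94.5 ± 13.1 to 138 ± 5.2 CPM (log2 0.54, adjusted p = 0.00711), and 26.8% of its exon bases are shared with another gene. The other called members, Mt1 and Mt2, lost the call without Con-pre 1, 2 or 3 or KO-pre 1, 3 or 4, and 73.5% of the exon bases of Mt2 are shared with another gene. Hdac4, a class II histone deacetylase and known CaMKII substrate, rose from 32.6 ± 6.23 to 61.8 ± 10.6 CPM (log2 0.93, adjusted p = 0.00564), with 22.4% of its exon bases shared with another gene. Of 5 red blood cell markers, Bpgm, which makes 2,3-bisphosphoglycerate, fell by 0.89 (adjusted p = 9.52e-05), and the list was called lower (camera adjusted p = 0.0487, and adjusted p = 0.504 with an estimated correlation). The blood list lost its call without Con-pre 2 (adjusted p = 0.131), Con-pre 4 (0.129), KO-pre 2 (0.253) or KO-pre 3 (0.0737). It also lost it with no filter on low counts (0.0602) and with trends of length and GC content removed (0.254).

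Falls before training included those of Actc1, the cardiac form of actin that developing muscle also makes, and Smox, spermine oxidase. Actc1 (ENSMUSG00000068614, chromosome 2, 114047282 to 114053548) fell from 1310 ± 536 to 190 ± 23.6 CPM (SD, n = 4; log2 -2.79, SE 0.227, adjusted p = 3.08e-09), and Smox from 274 ± 72 to 88 ± 25.3 CPM (log2 -1.64, adjusted p = 2.88e-07). Slc40a1, the iron exporter ferroportin, fell from 20.2 ± 5.25 to 6.84 ± 3.42 CPM, and Nr4a1, a nuclear receptor of the immediate early response, from 207 ± 54 to 88.6 ± 39.1 CPM. Cd24a, a surface glycoprotein, fell by 1.22 on the log2 scale. Ighm, the heavy chain of immunoglobulin M, fell by 1.20, and Dupd1, a phosphatase of skeletal muscle, by 1.29. Dupd1 (chromosome 14, 21676537 to 21714576) lies within 10 Mb of Camk2g. Htra4, a serine protease (chromosome 8, 25024929 to 25038962), rose from 5.18 ± 2.49 to 74.7 ± 27.1 CPM (log2 3.87, SE 0.39, adjusted p = 1.81e-07), although 32.9% of its exon bases are shared with another gene. Cpne2, a calcium-dependent phospholipid-binding protein, rose by 3.00, Odf3l2 by 2.94, Eda2r, a receptor of the tumour necrosis factor family, by 2.30, and Trp63, a transcription factor of the p53 family, by 1.88. In all, 273 of 7393 genes changed, 108 up and 165 down, against 1074 at an unadjusted p under 0.05. A change over 2-fold was seen in 61 of the called genes. The groups did not overlap for 677 genes (9.16%), where chance gives 2.86%. The median, mean and test direction differed in sign for 5 lists that were not called: CaM kinases (median 0.22, mean -0.15, camera adjusted p = 0.224), fast-fibre genes, fatty acid oxidation, secreted factors and tendon markers. Of the 59 named genes called, 19 lost the call without 1 of the libraries, Mt1 and Mt2 among them.

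KO against Con after training puts the same question to trained muscle. As lists, slow-fibre genes were again higher in KO, and glycolytic, respiratory, stress-response and matrix genes lower, the last pair with 4 of 13 and 4 of 21 members called. The respiratory, stress-response and matrix calls were lost with an estimated correlation. Of 14 slow-fibre genes 8 rose and 6 were not called (10 rose when adjusted over the list alone), with a median log2 change of 0.55 (camera adjusted p = 3.7e-12, and adjusted p = 0.0324 with an estimated correlation). Tnnt1 rose from 207 ± 44.7 to 407 ± 52 CPM (SD, n = 4; log2 0.98, SE 0.126, adjusted p = 8.47e-06), Tpm3 by 0.70, Atp2a2 by 0.65 and Myl2 by 0.60. The list of 18 fast-fibre genes was not called, and 11 of its genes had an unadjusted p under 0.05, 8 of them higher. Among 22 genes of glycolysis and glycogen 1 rose and 11 fell (1 and 12 over the list alone), with a median of -0.28 (camera adjusted p = 9.4e-13, and adjusted p = 0.00724 with an estimated correlation). Ldha fell from 2620 ± 124 to 1570 ± 169 CPM (log2 -0.74, SE 0.0731, adjusted p = 1.2e-07), Eno3 by 0.72, Tpi1 by 0.71 and Pgam2, the muscle phosphoglycerate mutase, by 0.57. Of 77 nuclear respiratory genes 24 fell and 53 were not called (41 fell when adjusted over the list alone), with a median of -0.20 (camera adjusted p = 1.05e-20, and adjusted p = 0.0944 with an estimated correlation). Sdhd of complex II fell from 234 ± 11.9 to 151 ± 25 CPM (log2 -0.62, adjusted p = 0.000472), Uqcr11 of complex III by 0.55 and Atp5g3 of ATP synthase by 0.37. Of 10 mitochondrially encoded genes 2 fell, mt-Cytb and mt-Nd1 (6 over the list alone), with a median of -0.22 (camera adjusted p = 0.00189, and adjusted p = 0.392 with an estimated correlation). The mt-Cytb value of -0.28 lost its call without Con-post 1, Con-post 2 or KO-post 2 (adjusted p = 0.0681, 0.0522 and 0.123). The mt-Nd1 value of -0.26 lost its call without Con-post 1, 2 or 3 (adjusted p = 0.137, 0.0558 and 0.0513) or KO-post 1, 2 or 4 (0.0536, 0.142 and 0.064). In the tricarboxylic acid cycle, Idh3a and Dlat, a subunit of pyruvate dehydrogenase, fell by 0.36 and 0.42 among 17 genes (6 fell when adjusted over the list alone; median -0.17, camera adjusted p = 0.00242, and adjusted p = 0.392 with an estimated correlation). The Dlat call was lost without Con-post 4 (adjusted p = 0.0585). Perm1, a regulator of mitochondrial genes in muscle, fell from 112 ± 19.8 to 68.9 ± 12.1 CPM (log2 -0.70, adjusted p = 0.00239).

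**Figure D2:**
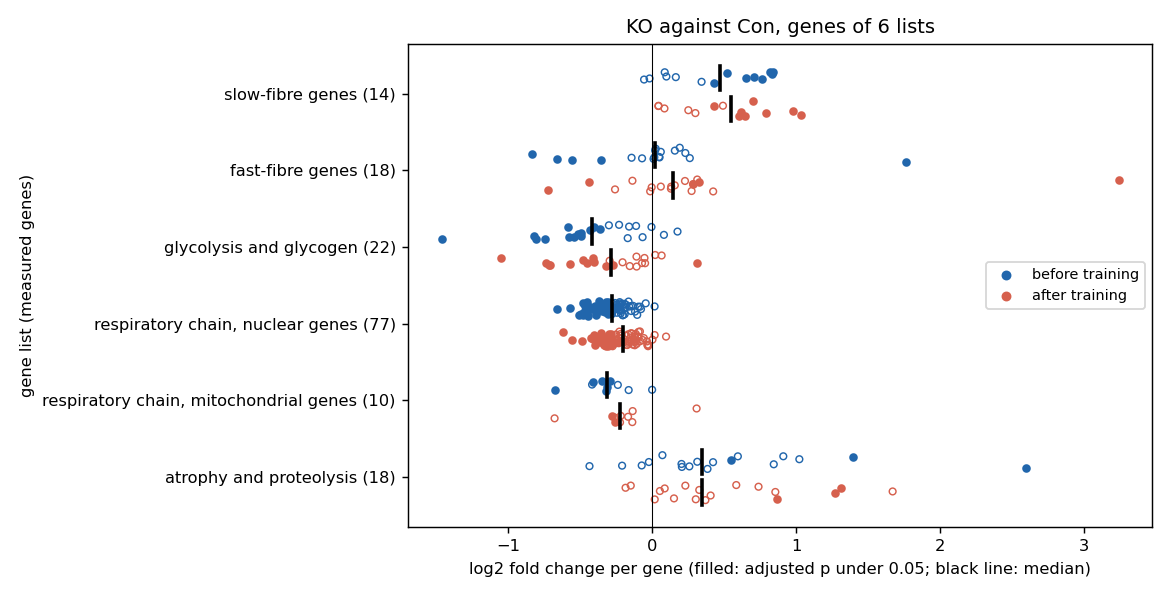
Log2 fold change of each measured gene, KO against Con, for 6 gene lists before and after training, where filled points are genes with an adjusted p under 0.05 and black lines are list medians. Slow-fibre genes lie mostly above 0 and genes of glycolysis and the respiratory chain mostly below it in both states.

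As lists, genes of muscle wasting and of calcium handling were higher in trained KO muscle than in trained Con muscle, with 3 of 18 and 4 of 20 members called higher. Both list calls were lost with an estimated correlation. The calcium handling list shares Atp2a2 with the slow-fibre list, so its call is not independent of the slow-fibre call. The list of atrophy and proteolysis (6 rose when adjusted over the list alone) had a median of 0.35 (camera adjusted p = 0.000116, and adjusted p = 0.331 with an estimated correlation). Trim63, the ubiquitin ligase MuRF1, rose from 221 ± 42.6 to 554 ± 302 CPM (SD, n = 4; log2 1.31, SE 0.3, adjusted p = 0.00945), but lost the call without KO-post 2 (adjusted p = 0.0549). Fbxo32, the ubiquitin ligase atrogin-1, rose by 1.27 (adjusted p = 0.0177) and lost the call without Con-post 1 or 3 (adjusted p = 0.0724 and 0.0522) or KO-post 1 or 2 (0.0997 and 0.0828). The other called member, Gadd45a, also lost it without KO-post 2 (adjusted p = 0.0519). Musk, the receptor kinase of the neuromuscular junction (chromosome 4, 58285960 to 58374303), rose from 32 ± 16.8 to 93.9 ± 31 CPM (log2 1.49, adjusted p = 0.0013). Among 20 genes of excitation-contraction coupling 4 rose (5 over the list alone), with a median of 0.05 (camera adjusted p = 0.00923, and adjusted p = 0.373 with an estimated correlation). Cacng1, a calcium channel subunit of muscle, rose from 216 ± 23 to 352 ± 51 CPM (log2 0.70, adjusted p = 0.000204), and Ryr1 from 1180 ± 63.9 to 1470 ± 128 CPM (log2 0.32). Atp2a1, the calcium pump of fast fibres, rose by 0.33 (adjusted p = 0.004), with 21.9% of its exon bases shared with another gene. The coupling list lost its call without KO-post 3 (adjusted p = 0.0606). Of 13 genes of the stress and unfolded protein response 4 fell (5 over the list alone), with a median of -0.25 (camera adjusted p = 0.00509, and adjusted p = 0.407 with an estimated correlation). Hsp90aa1, a cytosolic chaperone, fell from 122 ± 37.2 to 62.6 ± 16.3 CPM (log2 -0.96, adjusted p = 0.00817), and is the 1 member of the 4 that kept the call without Con-post 4 or KO-post 3. Of 21 extracellular matrix genes 4 fell (4 also over the list alone), with a median of -0.33 (camera adjusted p = 0.000228, and adjusted p = 0.37 with an estimated correlation). Col1a1, a chain of type I collagen, fell from 101 ± 33.1 to 39.1 ± 12.9 CPM (log2 -1.40, adjusted p = 0.014), and lost the call without Con-post 4 (adjusted p = 0.0751) or KO-post 3 (0.0578). Without either of those libraries Col1a2, Col3a1 and Ccn2, the other called matrix genes, lost it as well. The 13 fibroblast markers, of which 2 are also in the matrix list, were not called (median -0.11, camera adjusted p = 0.166), nor were the 6 tendon markers (median -1.05, camera adjusted p = 0.0648). Of the tendon markers, Thbs4, a thrombospondin that muscle also makes, fell from 81 ± 19.3 to 31.8 ± 9.53 CPM (log2 -1.36, adjusted p = 0.00168). With trends of length and GC content removed, 1 tendon marker was called lower and 1 higher. Of 9 secreted muscle factors 2 fell (4 over the list alone), with a median of -0.34 (camera adjusted p = 0.000116, and adjusted p = 0.0289 with an estimated correlation). They are Ostn, the peptide musclin, from 29.1 ± 3.36 to 7.21 ± 1.43 CPM (SE of the log2 change 0.25, adjusted p = 6.09e-06), and Vegfb, a growth factor, at -0.34 (adjusted p = 0.0112), which lost the call with no filter on low counts (adjusted p = 0.119, the highest of its alternatives). The 10 CaM kinase genes were called lower (camera adjusted p = 0.0147, and adjusted p = 0.323 with an estimated correlation) with a mean of -0.22 and a median of 0.04, since Camk2g and Camk2d fell and Camk2b rose. With trends of length and GC content removed, the lists of CaM kinases, mitochondrially encoded respiratory genes and coupling lost the call, and with no filter on low counts the CaM kinase list lost it too (adjusted p = 0.615).

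Actc1 was lower in KO after training too, and fell from 361 ± 115 to 29.8 ± 5.65 CPM (SD, n = 4; log2 -3.57, SE 0.276, adjusted p = 6.76e-10). Counts assigned to the mitochondrial glutamate tRNA mt-Te (chromosome M, 14071 to 14139) fell by 2.56. Slc40a1 fell by 1.97, Nr4a1 by 1.57, Dupd1 by 1.47 and Sh3kbp1, an adaptor of receptor uptake, by 1.42. Htra4, Odf3l2, Cpne2 and Eda2r rose by 4.61, 2.96, 2.65 and 1.70. Enho, the gene of the peptide adropin, rose by 1.38, Exoc7, a part of the exocyst, by 1.20, and Acsl3, a long-chain acyl-CoA synthetase, by 1.13. Across 7393 genes, 281 changed, 123 up and 158 down, against 1220 at an unadjusted p under 0.05, and without KO-post 2 the count was 176. With no filter on low counts the balance turned over, to 202 up and 162 down. Called genes over 2-fold numbered 59, and the groups did not overlap for 720 genes (9.74%, chance 2.86%). Both KO comparisons called 43 genes as higher and 80 as lower, where 1.8 and 3.53 would be shared by chance (Fisher's exact p = 1.11e-50 and 8.53e-97). Another 7 genes were called in opposite directions, all 7 of them pseudogenes. The 2 comparisons use different libraries, and across genes other than pseudogenes their log2 changes correlated at r = 0.408, where genes are not independent replicates. Fatty acid oxidation, MEF2 and calcineurin signalling, glucose uptake, immediate early genes, Schwann cell markers and pericyte markers had medians, means or test directions of different sign, with no call. Of the 58 named genes called, 18 lost the call without 1 of the libraries.

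Training in Con compares trained with untrained muscle of control mice. Of the lists tested, 8 of 21 matrix genes fell and 5 of 13 genes of the stress response rose. Secreted factors, fatty acid use and mitochondrially encoded respiratory genes were higher as lists, with 1 called member in each. With an estimated correlation the stress-response, fatty acid and mitochondrially encoded calls were lost. Of 21 matrix genes 8 fell and 13 were not called (10 fell when adjusted over the list alone), with a median log2 change of -0.62 (camera adjusted p = 7.02e-14, and adjusted p = 0.0452 with an estimated correlation). Col1a1 (chromosome 11, 94936224 to 94953042) fell from 282 ± 81.3 to 101 ± 33.1 CPM (SD, n = 4; log2 -1.45, SE 0.283, adjusted p = 0.00685) and Col1a2 from 363 ± 69.4 to 166 ± 57.9 CPM (log2 -1.12, adjusted p = 0.00818). Col3a1, the gene of type III collagen, fell by 0.91 and Sparc, a collagen-binding protein, by 0.76. Beside them, the 13 fibroblast markers had a median of -0.19 and were not called (camera adjusted p = 0.0809). Lists of 3 other cell types were called lower, the 6 tendon markers at a median of -0.66 (camera adjusted p = 0.0124), the 4 Schwann cell markers at -0.88 (0.00472) and the 12 endothelial markers at -0.23 (0.0256). With an estimated correlation they were not called (adjusted p = 0.353, 0.294 and 0.353). The tendon call was lost without Con-pre 1 (adjusted p = 0.0521) or Con-post 1 (0.0679), the Schwann call without Con-pre 3 (0.0729) and the endothelial call without Con-pre 1, Con-pre 4 or Con-post 3 (0.109, 0.0731 and 0.0782). Of 13 stress-response genes 5 rose (7 over the list alone), with a median of 0.51 (camera adjusted p = 6.83e-10, and adjusted p = 0.0935 with an estimated correlation). Hspa1a, an inducible form of the chaperone HSP70, rose from 10.1 ± 4.36 to 42.5 ± 21.4 CPM (log2 2.00, SE 0.398, adjusted p = 0.00802), but was not called by limma voom (adjusted p = 0.091, the highest of its alternatives). The other 4 called members lost the call without Con-pre 2, Con-post 2 or Con-post 4. Among 9 secreted factors Ostn rose (4 over the list alone), from 10.4 ± 5.97 to 29.1 ± 3.36 CPM (log2 1.53, adjusted p = 0.00084), with a list median of 0.27 (camera adjusted p = 0.000291, and adjusted p = 0.0452 with an estimated correlation). Of 27 genes of fatty acid uptake and oxidation, Fabp3, the fatty acid-binding protein of muscle, rose (4 over the list alone), from 87.2 ± 9.25 to 144 ± 22.8 CPM (log2 0.73, adjusted p = 0.00569). The list median was 0.18 (camera adjusted p = 3.86e-05, and adjusted p = 0.353 with an estimated correlation). Of 10 mitochondrially encoded respiratory genes 9 had a value above 0 and 1 was called (6 over the list alone), with a median of 0.23 (camera adjusted p = 2.01e-05, and adjusted p = 0.294 with an estimated correlation). The called gene, mt-Atp6, has pseudogene copies, which makes its change uncertain, and it lost the call without Con-pre 1, 2, 3 or 4, KO-pre 3 or 4 or Con-post 1, 3 or 4 (adjusted p from 0.0563 to 0.14).

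Among 18 fast-fibre genes 5 fell after training in Con (6 over the list alone), with a median of -0.14 (camera adjusted p = 0.000291, and adjusted p = 0.294 with an estimated correlation). Mylpf, a fast myosin light chain, had a log2 change of -0.34 (adjusted p = 0.0206), lost without Con-pre 1 or 3 (adjusted p = 0.0681 and 0.0945) or Con-post 1 or 4 (0.0682 and 0.107). Casq1, Tnnc2 and Pvalb also lost the call without Con-post 4. Of 20 genes of excitation-contraction coupling 2 fell (5 over the list alone; median -0.11, camera adjusted p = 0.00275, and adjusted p = 0.294 with an estimated correlation), and both lost the call without Con-pre 1 or Con-post 4. Nuclear respiratory genes were called lower as a list, unlike the mitochondrially encoded genes, with 5 of 77 called lower (20 over the list alone), a median of -0.05 and a camera adjusted p of 0.00288 (adjusted p = 0.627 with an estimated correlation). Cox7c of complex IV fell from 684 ± 46.4 to 524 ± 33.4 CPM (SD, n = 4; log2 -0.38, SE 0.073, adjusted p = 0.0058). The nuclear list lost its call without Con-pre 4 (adjusted p = 0.119). Immediate early genes (median 0.39), antioxidant genes (0.13) and red blood cell markers (0.65) were called higher as lists, with camera adjusted p-values of 0.0246, 0.0218 and 0.00787. With an estimated correlation the adjusted p-values were 0.353, 0.353 and 0.296. In each, edgeR called 0 members over all genes, while 4, 7 and 4 members had an unadjusted p under 0.05. The immediate early call was lost without Con-pre 1 (adjusted p = 0.184) or Con-post 4 (0.143), and the antioxidant call without Con-pre 2, Con-pre 3 or Con-post 2 (0.074, 0.0619 and 0.0911). With trends of length and GC content removed, the immediate early, antioxidant, endothelial and red blood cell lists lost the call. G0s2, an inhibitor of triglyceride lipase (chromosome 1, 193272161 to 193273217), rose from 16 ± 3.22 to 54.9 ± 6.03 CPM (log2 1.74, SE 0.241, adjusted p = 9.71e-05). Rasd2, a small GTPase, rose from 12.2 ± 2.74 to 31.3 ± 9.62 CPM (log2 1.32, adjusted p = 0.0058). Actc1 fell from 1310 ± 536 to 361 ± 115 CPM (log2 -1.87, SE 0.215, adjusted p = 4.22e-06), and Nrep, a protein first described in neurons, from 219 ± 38.5 to 107 ± 19.4 CPM. Man2a2, a Golgi mannosidase, fell by 0.94 on the log2 scale. In all, 67 genes changed, 26 up and 41 down, against 950 at an unadjusted p under 0.05, and 13 of the 67 are pseudogenes. The count was 40 with pseudogenes left out and 161 with no filter on low counts. The groups did not overlap for 568 genes (7.68%, chance 2.86%). Leaving out Con-post 4, Con-pre 1 or Con-pre 2 lowered the count to 34, 39 or 42, and 21 of the 34 named genes called lost the call without 1 of the libraries. Lists whose median, mean and test differed in sign were not called (CaM kinases, slow-fibre genes, MEF2 and calcineurin signalling, glucose uptake, atrophy and interferon response).

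Training in KO puts the question of training to muscle without the kinases. As lists, matrix genes were lower in KO as well, mitochondrially encoded respiratory genes higher (7 of 10 called) and genes of calcium handling lower (6 of 20 called). The last pair of calls was lost with an estimated correlation. Of 21 matrix genes 11 fell and 10 were not called (15 fell when adjusted over the list alone), all 21 had a value below 0, and the median log2 change was -0.84 (camera adjusted p = 1.31e-31, and adjusted p = 0.00497 with an estimated correlation). Col1a1 fell from 301 ± 178 to 39.1 ± 12.9 CPM (SD, n = 4; log2 -2.96, SE 0.31, adjusted p = 7.03e-07), Col1a2 by 2.13, Col3a1 by 1.58 and Sparc by 1.35. Beside them, 4 of 13 fibroblast markers fell (4 also over the list alone), 2 of which are the collagens Col1a1 and Col3a1, with a median of -0.36 (camera adjusted p = 1.14e-06, and adjusted p = 0.101 with an estimated correlation). The others, Serpinf1 and Smoc2, lost the call without KO-pre 1 or 4 or KO-post 2, 3 or 4. Of 6 tendon markers 4 fell (5 over the list alone), with a median of -1.86 (camera adjusted p = 1.83e-05, and adjusted p = 0.163 with an estimated correlation). Fmod, a proteoglycan of tendon, fell from 49.2 ± 38 to 13.3 ± 2.22 CPM (log2 -1.88, adjusted p = 0.00625), and lost the call without KO-pre 1 (adjusted p = 0.0653), which held 106 CPM against 25.4 to 37.6 in the other KO-pre libraries. The other 3 called markers, Chad, Tnmd and Kera, lost it there too. Of 4 Schwann cell markers 2 fell (4 over the list alone), among them Pmp22, a gene of myelin, from 52.7 ± 32.7 to 17.4 ± 3.29 CPM (log2 -1.57, adjusted p = 0.00625), with a list median of -1.41 (camera adjusted p = 0.000189, and adjusted p = 0.163 with an estimated correlation). Pmp22 lost the call without KO-pre 1 (adjusted p = 0.0651). Of 12 endothelial markers, each with a value below 0, 3 fell (6 over the list alone), with a median of -0.56 (camera adjusted p = 2.07e-06, and adjusted p = 0.105 with an estimated correlation). Ptprb, a phosphatase of endothelium, fell from 68.5 ± 9.79 to 38.3 ± 7.08 CPM (log2 -0.83, adjusted p = 0.00155), and lost the call with trends of length and GC content removed (log2 -0.55, adjusted p = 0.0514, the highest of its alternatives). The other called members, Fabp4 and Cdh5, lost the call without KO-pre 4 or KO-post 3. The pericyte genes Rgs5 and Pdgfrb fell by 0.47 and 1.22, from 208 ± 7.61 to 149 ± 8.83 CPM and from 16.3 ± 1.36 to 6.9 ± 1.78 CPM, in a list that was not called (median -0.37, camera adjusted p = 0.144). Of 3 members of that list with an unadjusted p under 0.05, 1 was higher.

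**Figure D3:**
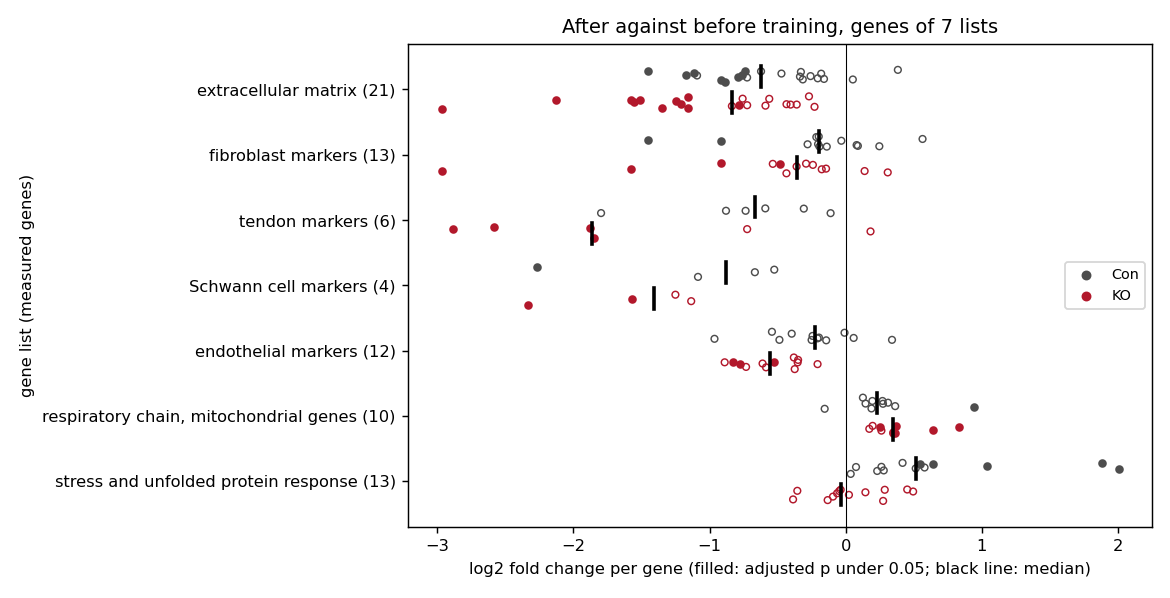
Log2 fold change of each measured gene, after against before training, for 7 gene lists in Con and KO, where filled points are genes with an adjusted p under 0.05 and black lines are list medians. Matrix genes lie mostly below 0 and mitochondrially encoded respiratory genes mostly above 0 in both genotypes.

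Of 10 mitochondrially encoded respiratory genes 7 rose with training in KO (8 over the list alone), with a median of 0.35 (camera adjusted p = 1.54e-08, and adjusted p = 0.122 with an estimated correlation). Among them, mt-Nd1 rose by 0.35 on the log2 scale, from 20500 ± 818 to 26000 ± 1480 CPM (SD, n = 4; SE 0.07, adjusted p = 0.00386). The 77 nuclear respiratory genes were not called as a list (median 0.00, camera adjusted p = 0.647), with 4 called higher and 3 lower (the same counts over the list alone). Among the 3, Ndufa1 of complex I fell from 118 ± 9.54 to 85.7 ± 5.67 CPM (log2 -0.45, SE 0.0958, adjusted p = 0.00538). Among 20 genes of excitation-contraction coupling 1 rose and 6 fell (3 and 7 over the list alone), with a median of -0.17 (camera adjusted p = 0.0297, and adjusted p = 0.453 with an estimated correlation). Casq1, the calcium-storing protein of the sarcoplasmic reticulum, fell from 1690 ± 158 to 1230 ± 82.5 CPM (log2 -0.45, adjusted p = 0.00166), and Cacna2d1, a calcium channel subunit, fell by 0.56. Atp2a1 rose from 2270 ± 147 to 2940 ± 131 CPM (log2 0.37, adjusted p = 0.00132). The coupling list lost its call without Con-pre 1 or 2 (adjusted p = 0.0535 and 0.0508), KO-pre 1, 2 or 3 (0.0687, 0.146 and 0.0913) or KO-post 1 or 2 (0.239 and 0.0815), and with no filter on low counts (0.189). Genes of fatty acid uptake and oxidation (median 0.14, camera adjusted p = 0.0104) and red blood cell markers (0.53, camera adjusted p = 0.0104) were called higher as lists, with adjusted p = 0.572 and 0.355 with an estimated correlation. In these lists edgeR called 0 members over all genes, while 8 and 3 had an unadjusted p under 0.05. The fatty acid call was lost without KO-pre 1 (adjusted p = 0.0687) or KO-post 1 (0.144), and the blood call without KO-pre 2, KO-post 1 or KO-post 2 (0.0726, 0.0627 and 0.0815). Both lists also lost it with trends of length and GC content removed.

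Rasd2 rose with training in KO, from 2.34 ± 1.72 to 20.7 ± 4.89 CPM (SD, n = 4; log2 3.10, SE 0.374, adjusted p = 5.92e-06). Tmem37, a relative of calcium channel subunits, rose by 1.34, Gpx3, a secreted glutathione peroxidase, by 1.20 and Myod1, the transcription factor of muscle precursors, by 1.16. Pnpla2, the triglyceride lipase that G0s2 inhibits, rose from 155 ± 17.3 to 214 ± 21.5 CPM (log2 0.47, adjusted p = 0.00691), and Grb10, an adaptor that dampens insulin signalling, fell from 42.4 ± 12.1 to 17.9 ± 4.09 CPM (log2 -1.17, adjusted p = 0.00136). Actc1 fell from 190 ± 23.6 to 29.8 ± 5.65 CPM (log2 -2.65, SE 0.284, adjusted p = 7.95e-07), and Rftn1, a protein of membrane rafts, by 1.72. In all, 286 genes changed, 122 up and 164 down, against 1323 at an unadjusted p under 0.05. With no filter on low counts 223 were up and 178 down, and without KO-post 4 158 were up and 155 down, so the balance turned over. Called genes over 2-fold numbered 61, and the groups did not overlap for 752 genes (10.2%, chance 2.86%). Without KO-pre 1 the count was 165, and 22 of the 52 named genes called lost the call without 1 of the libraries. Training called 7 genes as higher and 23 as lower in both genotypes, where 0.429 and 0.91 would be shared by chance (Fisher's exact p = 1.42e-07 and 2.7e-28), and 5 pseudogenes in opposite directions. Across genes other than pseudogenes the training effects in Con and KO correlated at r = 0.373. Here too the estimates of spread are shared, so the counts expected by chance may be too low, and genes are not independent replicates. Fast-fibre genes, atrophy, stress response, secreted factors and leukocyte markers had medians, means or test directions of different sign, with no call.

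The difference between the training effects, KO minus Con, asks which responses to training depend on the genotype. It was called for few genes, and of those named here G0s2 and mt-Te kept the call without any 1 of the 16 libraries. G0s2 (ENSMUSG00000009633) rose with training in Con, from 16 ± 3.22 to 54.9 ± 6.03 CPM, and had 30.1 ± 12.5 and 24 ± 6.38 CPM in KO-pre and KO-post (SD, n = 4), a difference of -2.02 ± 0.339 on the log2 scale (SE; adjusted p = 0.00158). The tRNA mt-Te had 32.4 ± 1.3 and 38.4 ± 5.66 CPM in Con, and 24.2 ± 3.56 and 6.18 ± 2.19 CPM in KO (difference -2.15, SE 0.273, adjusted p = 2.09e-05). In all, 20 genes were called, 7 higher and 13 lower, against 498 at an unadjusted p under 0.05. The count was 3, all 3 lower, with pseudogenes left out, 8 with their counts added to the coding gene, 48 with no filter on low counts and 13 without Con-pre 4. Of the 20 genes, 14 are pseudogenes and 5 are protein-coding, all 5 lower. The protein-coding genes include G0s2, Hsp90aa1 (-1.43, adjusted p = 0.045), Wdr82 (-1.34, adjusted p = 0.0265) and Ccar1 (-0.77, adjusted p = 0.0433). Hsp90aa1 lost the call without Con-pre 1, 2 or 4 (adjusted p = 0.135, 0.126 and 0.146), KO-pre 1 or 4 (0.134 and 0.157), Con-post 2, 3 or 4 (0.118, 0.141 and 0.143) or KO-post 1, 2 or 3 (0.0639, 0.105 and 0.141). Wdr82, a subunit of a histone methyltransferase, lost it without Con-pre 1, 3 or 4 (0.0656, 0.0739 and 0.0813), KO-pre 1 or 2 (0.0531 and 0.0677), Con-post 2, 3 or 4 (0.0757, 0.0821 and 0.0571) or KO-post 1, 3 or 4 (0.0592, 0.053 and 0.0614). Ccar1, a transcriptional coactivator, lost it without any 1 of 14 libraries, all but Con-post 1 and KO-pre 4, with adjusted p-values from 0.0511 to 0.217. No CaMKII gene was called (adjusted p between 0.707 and 0.972).

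As lists, 9 of 30 differed in their training effect by camera and 0 with an estimated correlation, where 3 lists had an unadjusted p under 0.05. Stress-response genes were lower in KO relative to Con, with 13 of 13 values below 0, a median of -0.37 and 1 called member, Hsp90aa1 (4 over the list alone; camera adjusted p = 7.8e-06, and adjusted p = 0.393 with an estimated correlation). Extracellular matrix genes had a median of -0.47 (5 lower over the list alone; camera adjusted p = 2.13e-05, and adjusted p = 0.393 with an estimated correlation). Col1a2 and Sparc, the members with the most counts, had differences of -1.01 (adjusted p = 0.419) and -0.58 (adjusted p = 0.516). Fibroblast markers (median -0.26, 2 lower over the list alone, camera adjusted p = 0.00408), endothelial markers (-0.38, 0.0261), secreted factors (-0.29, 1 lower over the list alone, 0.0108) and immediate early genes (-0.32, 1 lower over the list alone, 0.0402) were called lower. With an estimated correlation their adjusted p-values were 0.393, 0.516, 0.393 and 0.516. Fast-fibre genes (0.13, camera adjusted p = 0.00145), nuclear respiratory genes (0.08, 0.00408) and glycolysis (0.09, 0.0124) were called higher, with adjusted p = 0.436, 0.786 and 0.406 with an estimated correlation. In the lists other than the stress response edgeR called 0 members over all genes, while 6 matrix genes, 2 fibroblast and 2 endothelial markers, 4 secreted factors, 2 immediate early genes, 4 fast-fibre genes, 6 nuclear respiratory genes and 5 genes of glycolysis had an unadjusted p under 0.05. The respiratory call was lost without KO-pre 1 (adjusted p = 0.105), the secreted factor call without KO-post 3 (0.0525), and the glycolysis call without Con-post 4 (0.0739) or KO-post 3 (0.0596). The immediate early call was lost without Con-pre 1, KO-pre 1, Con-post 4 or KO-post 3 (0.183, 0.0552, 0.182 and 0.235), and the endothelial call without Con-pre 2, KO-pre 1, KO-pre 4, Con-post 4, KO-post 2 or KO-post 3 (0.12, 0.0552, 0.115, 0.135, 0.0673 and 0.117). With trends of length and GC content removed, the fast-fibre, nuclear respiratory, glycolysis and endothelial lists lost the call (adjusted p = 0.0705, 0.465, 0.0841 and 0.0705). With no filter on low counts the endothelial list lost it too (0.0917). Slow-fibre genes, tricarboxylic acid cycle, excitation-contraction coupling, atrophy and blood markers had medians, means or test directions of different sign, with no call.

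Pseudogenes were called more often than other genes in each of the 6 comparisons. Of 72 tested, 17 were called in KO against Con before training (23.6%, against 3.5% of other genes, Fisher's exact p = 5.86e-10) and 16 after it (22.2% against 3.62%, exact p = 7.49e-09). Training called 13 in Con (18.1% against 0.738%, exact p = 3.84e-14) and 14 in KO (19.4% against 3.72%, exact p = 4.85e-07). The difference in training effect called 14 (19.4% against 0.082%, exact p = 6.71e-25) and the averaged KO comparison 17 (23.6% against 7.99%, exact p = 4.71e-05). The exact tests treat pseudogenes as independent, but several of those called are copies of mitochondrially encoded genes. Such copies may move together, so these p-values may be too small. The 4 named here were chosen after their values were seen. Gm13292 matches Gapdh at 99.0% identity over 30.0% of its length, too short a match for its counts to be added to Gapdh. Gm13292 had 145 to 176 CPM in Con-pre, 109 to 130 in KO-pre, 0 to 0.942 in Con-post and 159 to 192 in KO-post. Gapdh, a gene of glycolysis, lay between 298 and 475 CPM in all 16 libraries. Rps2-ps6, a copy of the ribosomal protein gene Rps2, had 12.7 to 23.7 CPM in Con-pre, 0 to 0.971 in KO-pre, 0 in all 4 Con-post libraries and 4.61 to 7.26 in KO-post. Gm6139, another copy of Rps2, had 0 to 0.635, 4.85 to 6.36, 12 to 15.1 and 0 to 2.55 CPM in the same order of groups, and Rps2 lay between 533 and 755 CPM. Gm28437, a copy of mt-Co3, had 3430 to 3760, 313 to 367, 3980 to 4840 and 847 to 1010 CPM. Reads of such copies can be counted for the parent gene or the reverse. The changes of mt-Co1, mt-Co2, mt-Co3, mt-Atp6, mt-Nd2, mt-Nd4 and mt-Nd5, which have such copies, are thus uncertain too. The calls of the mitochondrially encoded list, which holds these genes, share this limit. In KO against Con after training, Gm28437 had a log2 change of -2.23 and mt-Co3 of 0.31. With the counts of copies added, the log2 change of mt-Co3 by training in KO went from 0.83 to 1.45.

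**Figure D4:**
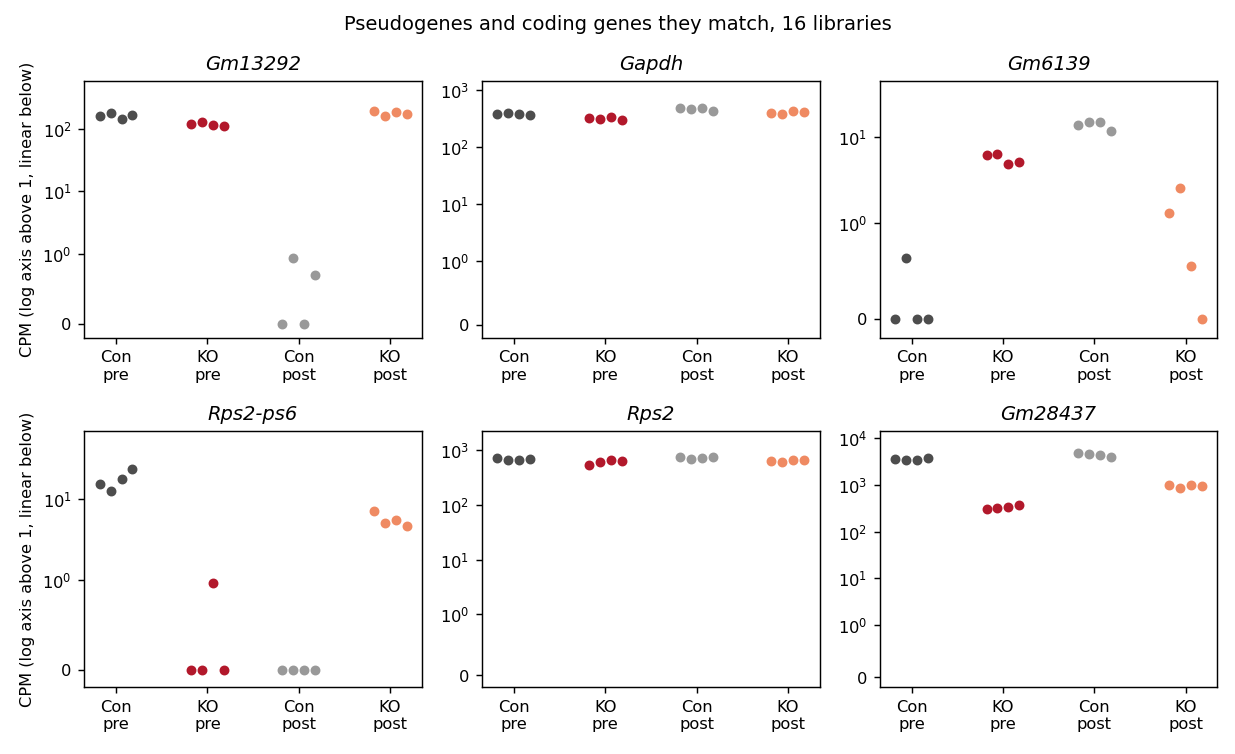
CPM of 4 pseudogenes and 2 coding genes in each of 16 libraries, by group, on a log axis above 1 CPM and a linear axis below it. Gm13292 is near 0 in the 4 Con-post libraries, while Gapdh lies between 298 and 475 CPM.

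KO against Con averaged over both training states uses all 16 libraries and asks which transcripts differ by genotype on average. It called 602 genes, 261 up and 341 down, against 1500 at an unadjusted p under 0.05. Of 77 nuclear respiratory genes 57 fell and 20 were not called (66 fell when adjusted over the list alone), with a median of -0.25 (camera adjusted p = 1.77e-40, and adjusted p = 0.0166 with an estimated correlation), as did 14 of 22 genes of glycolysis and glycogen (15 over the list alone; median -0.36, camera adjusted p = 3.76e-25, and adjusted p = 0.000283 with an estimated correlation). Of 14 slow-fibre genes 8 rose (9 over the list alone), with a median of 0.58 (camera adjusted p = 4.16e-15, and adjusted p = 0.0166 with an estimated correlation). Ldha fell by 0.78 (SE 0.0517, adjusted p = 1.9e-11), Cox6b1 of complex IV by 0.40 and Mdh2, malate dehydrogenase of mitochondria, by 0.21, and Tnnt1 rose by 0.87 (SE 0.0888, adjusted p = 8.64e-08). Of 18 genes of atrophy and proteolysis 8 rose (11 over the list alone), among them Trim63 by 1.11 (SE 0.211, adjusted p = 0.000644), Fbxo32 by 1.15 (SE 0.226, adjusted p = 0.00101) and Mt1, a metallothionein, by 1.13. The list median was 0.33 (camera adjusted p = 7.46e-06, and adjusted p = 0.2 with an estimated correlation). Excitation-contraction coupling was called higher, with 5 of 20 genes up (6 over the list alone; median 0.06, camera adjusted p = 0.00501, and adjusted p = 0.278 with an estimated correlation). Mitochondrially encoded respiratory genes (5 of 10 down, 8 over the list alone, median -0.27) and the tricarboxylic acid cycle (5 of 17 down, 7 over the list alone, median -0.12) were called lower, with camera adjusted p = 1.22e-06 and 0.000544, and adjusted p = 0.192 and 0.279 with an estimated correlation. Of 9 secreted factors 3 fell (3 also over the list alone; median -0.20, camera adjusted p = 0.02, and adjusted p = 0.151 with an estimated correlation, with the call also lost with no filter), including Il15, the cytokine interleukin-15, from 9.24 ± 4.92 to 3.34 ± 0.917 CPM before and 12.1 ± 1.44 to 5.62 ± 2.67 CPM after training (SD, n = 4; adjusted p = 0.00284). Ppp3ca, the catalytic subunit of calcineurin, rose by 0.23 (adjusted p = 0.00259), and Sod2, the superoxide dismutase of mitochondria, fell by 0.30 (adjusted p = 0.000236). The CaM kinase list (median 0.07, mean -0.18, test direction lower, camera adjusted p = 0.0325, and adjusted p = 0.278 with an estimated correlation) reversed its direction with no filter on low counts (adjusted p = 0.813). It lost its call with trends of length and GC content removed (adjusted p = 0.944, the highest of its alternatives) and without Con-pre 3 (adjusted p = 0.0617), KO-pre 2 (0.0501), KO-pre 4 (0.0557) or KO-post 3 (0.0529). The red blood cell list (median -0.27, camera adjusted p = 0.024, and adjusted p = 0.377 with an estimated correlation) lost it without KO-pre 2 (0.0706), Con-post 2 (0.0505) or KO-post 3 (0.11), and with trends of length and GC content removed. Fatty acid oxidation, regulators of mitochondrial biogenesis, MEF2 and calcineurin signalling, the circadian clock, endothelial markers and fibroblast markers had medians, means or test directions of different sign, with no call.

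Of the 30 lists tested, 10 were not called in any of the 6 comparisons. The smallest adjusted p-values by camera were 0.0615 for pericyte markers in training in Con, 0.0895 for lipid synthesis and storage in KO before training, 0.0905 for denervation and the neuromuscular junction in KO after training, and 0.158 for regeneration, 0.18 for the circadian clock, 0.357 for MEF2 and calcineurin signalling and 0.436 for regulators of mitochondrial biogenesis in training in KO. For leukocyte markers, glucose uptake and the interferon response they were 0.327, 0.365 and 0.561.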

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

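The tests of technical explanations below were chosen after the results were seen, while the regroupings of libraries were planned.

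In 21 of the 284 groups of 4 libraries tested, over 68 named genes and the total count and the mitochondrial and pseudogene shares of the libraries, 1 library lay far from the other 3 by Dixon's test. Chance gives about 1 in 20 such groups (5%), so the 21 are somewhat more than chance would give, and 18 of them are given here. Each value below is the gap to the nearest library as a share of the range of the group. In KO-post 1, Mt2 had 45.6 CPM against 4.1 to 6.11 in the others (0.952), Col3a1 63.4 against 42.7 to 43.3 (0.971) and Fabp3 161 against 102 to 111 (0.849), while Exoc7 was low, with 83.9 against 94.2 to 94.4 (0.986). In KO-post 2, Alpk3 had 176 CPM against 153 to 154 (0.95), and in KO-post 3, Fmod had 16.7 against 11.9 to 12.5 (0.863). KO-pre 1 had high levels of Fmod, 106 CPM against 25.4 to 37.6 (0.848), and Zmym4, 19.4 against 13.5 to 14.3 (0.871). Con-pre 4 had 481 CPM of Trim63 against 219 to 227 (0.966). In Con-pre 2, Apeh had 15.9 CPM against 13.3 to 13.7 (0.855) and Wdr82 16.5 against 11.5 to 11.8 (0.925). In Con-pre 1, mt-Te had 34.4 CPM against 31.7 to 31.9 (0.949). Con-post 1 was low in Hsp90aa1, 66.6 CPM against 138 to 145 (0.911), and in Ube2m, 82.3 against 96 to 98.3 (0.858), and high in Slc40a1, 29.8 against 19.8 to 20.7 (0.912). In Con-post 3, Camk2d had 55.3 CPM against 38.9 to 40.5 (0.902). Con-post 4 was low in Col15a1, 9.19 CPM against 14 to 14.9 (0.852), and high in Fmod, 41.7 against 21.9 to 24.8 (0.854).

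The training effect differed between KO and Con by the test of the difference itself for 7 genes chosen by the rule for named genes, 6 of which are given here. The log2 differences, KO minus Con, were -2.15 for mt-Te, -2.02 for G0s2, -1.43 for Hsp90aa1, -1.34 for Wdr82, -1.04 for the pseudogene Hmgb1-ps8 and -0.773 for Ccar1. Among these, mt-Te and G0s2 kept the call without any 1 library, though the RNA behind the mt-Te counts is uncertain. Hmgb1-ps8 lost it without any 1 of 12 libraries (Con-pre 1 to 4, KO-pre 1 and 4, Con-post 1, 3 and 4, and KO-post 1, 3 and 4), with adjusted p from 0.0511 to 0.123. Hsp90aa1 lost it without any 1 of 11 libraries (Con-pre 1, 2 and 4, KO-pre 1 and 4, Con-post 2, 3 and 4, and KO-post 1 to 3), with adjusted p from 0.0639 to 0.157. Wdr82 lost it without any 1 of 11 (Con-pre 1, 3 and 4, KO-pre 1 and 2, Con-post 2, 3 and 4, and KO-post 1, 3 and 4), with adjusted p from 0.053 to 0.0821. Ccar1 lost it without any 1 of 14, all but KO-pre 4 and Con-post 1, with adjusted p from 0.0511 to 0.217. For 9 lists the difference passed by camera, with adjusted p = 7.8e-06 for the stress response, 2.13e-05 for the extracellular matrix, 0.00145 for fast-fibre genes, 0.00408 for nuclear respiratory genes and also for fibroblast markers, 0.0108 for secreted factors, 0.0124 for glycolysis, 0.0261 for endothelial markers and 0.0402 for immediate early genes. No list passed with an estimated correlation or by fry.

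When the 8 libraries of a comparison were regrouped into all 35 possible splits of 4 against 4, only the real split (1 split) gave as many called genes. The real counts, from the 8 libraries alone, were 293 in KO against Con before training, 247 after it, 95 for training in Con and 202 for training in KO, against at most 8, 11, 7 and 7 in the other splits. Libraries of a group were thus more alike than a chance assignment of these libraries to groups would give, and 1 of 35 is the smallest share these splits can give. Each group is 1 pool and its replicates may be technical, so the splits do not test chance differences between pools or animals. Of 100 regroupings of the 16 libraries for the averaged comparison, 1, the real one, reached 602 genes, and the highest other gave 128, with the same limit. For the difference in training effect 3 of 100 regroupings, the real one included, gave at least 20 genes, and the highest other gave 111. These regroupings break up the training effect within each genotype as well as its difference, so they do not test the difference alone and leave open whether chance gave its count. The regrouping with 111 kept 3 of 4 Con-pre labels and 0 of 4 KO-pre labels, close to a comparison of all libraries before with all after training.

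Pseudogenes changed more often than other genes in each comparison. A strain difference between Con and KO would leave training within Con without such changes, but 18.1% of tested pseudogenes were called there. Reads passed on from the parent gene at a fixed share would give both the same log2 change, but the median ratio of the parent's change to the pseudogene's was 0.12 before training. The labels give 1 pool per group but not whether the pools were amplified apart, so an effect of the pools, if there was one, cannot be told apart from the groups, and 7 of the 12 pseudogenes called in both KO comparisons went in opposite directions. Errors of reads within a pool may be a source of these changes, and no biological explanation was tested.

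As lists, slow-fibre genes were higher and genes of glycolysis and the respiratory chain lower in KO in both states, though with an estimated correlation the calls of slow-fibre genes before training (adjusted p = 0.0603), nuclear respiratory genes after it (0.0944) and mitochondrially encoded genes in both (0.196 and 0.392) were lost. With trends of transcript length and GC content removed the nuclear respiratory genes still had a median of -0.216 before training, with 73 of 77 below 0, which argues against such a bias as the whole cause. More slow fibres in the piece of muscle would raise respiratory transcripts, yet 76 of 77 nuclear respiratory genes had a change below 0. More slow fibres alone thus do not account for that part. That value is part of the pattern itself, so it cannot exclude more slow fibres beside a separate fall in respiratory transcripts. For the slow-fibre and glycolytic parts the explanation stays open. More slow fibres would also lower fast-fibre genes, but that list was not called in either state. Of its 18 genes, 6 had an unadjusted p under 0.05 before training, 2 of them higher, and 11 after it, 8 of them higher. These values differ between the states and do not decide it. The changes before and after training, from different pools, correlated at r = 0.408 across genes other than pseudogenes, but with 1 pool per group, genotype and pool cannot be told apart. The loss of the kinases may lie behind the pattern, as a hypothesis that stays open beside the pools.

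As a list, genes of the extracellular matrix were lower after training in both genotypes. With trends of length and GC content removed the median by training in KO was -0.695, with all 21 genes below 0, which argues against that bias as the whole cause. Fewer fibroblasts would lower all their transcripts alike, but the 11 fibroblast markers outside the matrix list had a median of -0.291 in KO against -0.84 for the matrix genes (permutation p = 0.00018). The permutation treats genes as independent, which they may not be. Dcn, an abundant marker, had 515 ± 98.1 CPM before and 466 ± 42.1 CPM after training. Serpinf1 and Smoc2 of the same marker list were called lower, though those calls were lost without some single libraries. Schwann cell (median -1.41) and endothelial markers (-0.558) were called lower in KO as lists too, calls that were lost with an estimated correlation. Less tendon in the trained pieces could account for part of the fall, since the 6 tendon markers had a median change of -1.86 in KO, with 4 called lower, though the calls of Fmod, Chad, Tnmd and Kera were lost without KO-pre 1 (adjusted p = 0.0653, 0.073, 0.0708 and 0.159). Pool, and the age of the mice, were not separated from training, and the correlation of the training changes in Con and KO (r = 0.373) cannot tell them apart.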

How the results depend on the processing

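The alternatives without pseudogenes, with copies summed and with length and GC trends removed were chosen after the data had been seen, while the others were planned. The 9 called changes of Camk2g, Camk2d and Camk2b kept their direction and their call under each alternative run. The counts of changed genes stayed within 1.5 times under DESeq2, RLE scaling, voom weights, the replicate block, the 2 groups alone, mitochondrial genes left out and the length and GC correction. A similar count could hold other genes. DESeq2 called 78 genes for training in Con, of which 38 were among the 67 of edgeR. With the length and GC correction 194 were called for training in KO, of which 145 were among the 286. For KO against Con before training, 224 of 234 DESeq2 calls were shared. With no filter, training in Con had 161 genes (67 with it) and the difference in training effect 48 (20 with it), and the cause was not tested. With pseudogenes left out these counts were 40 and 3, and with copies summed the difference had 8 genes. The 13 and 14 pseudogenes among the calls account for only part of these falls, and the cause of the rest was not tested. The counts moved without 1 library: 176 to 314 genes for KO after training (lowest without KO-post 2, 281 with all), 34 to 98 for training in Con (Con-post 4, 67 with all; 39 and 42 without Con-pre 1 and 2, 98 without KO-post 1), 165 to 313 for training in KO (KO-pre 1, 286 with all) and 13 to 22 for the difference (Con-pre 4). The cause was not tested.

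Of 30 lists, camera called 8 and 11 in the KO comparisons before and after training, 14 and 9 for training in Con and KO, 9 for the difference and 10 for the average. With an estimated correlation the counts were 2, 3, 2, 1, 0 and 3, since that test allows for correlation between the genes of a list. With fry, which asks another question, they were 4 for KO before training, 7 and 5 for training in Con and KO and 0 for the difference. With no filter training in KO had 14 lists, and with length and GC trends removed the difference had 5. The CaM kinase list in the averaged comparison reversed with no filter (adjusted p = 0.813). Without 1 library KO after training had 10 to 17 lists (17 without KO-post 1) and the difference 5 to 11 (5 without KO-post 3), and the cause was not tested. Of 61 list calls, 50 were lost with an estimated correlation, 30 with fry, 17 with length and GC trends removed and 5 with no filter. Of 285 calls of named genes, 28 were lost with length and GC trends removed, 20 with voom weights, 19 with no filter, 18 with the replicate block and 4 with RLE scaling. DESeq2 gave an adjusted p for 240 of the 285, and 22 of these 240 were lost. Lower depth was not tested as an alternative, since no library fell under the depth set for leaving it out. At this depth the self-test called 6 of 100 genes with a 1.5-fold difference in training effect, so small differences can be missed.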

Other observations

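The tests of genes near the targeted genes were chosen after the results were seen. Within 10 Mb of Camk2g, 10 of 57 tested genes (17.5%) were called in the averaged KO comparison, against 8.04% of genes elsewhere (Fisher's exact p = 0.0231, unadjusted). Before training 4 of 57 were called there (exact p = 0.153), and after training 3 (exact p = 0.477). Dupd1 and Myoz1, named above as lower in KO, lie in this stretch. Within 10 Mb of Camk2d, 4 of 42 were called in the averaged comparison (exact p = 0.578). These 6 tests, with 3 for each of the 2 genes, were not adjusted for their number.

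Whether the replicate numbers pair libraries across groups was checked with correlations after removing the group means. For libraries with the same number these ranged from -0.247 to 0.149 with a mean of -0.0258. For each library, correlations were also averaged over the libraries of each number in the other groups. The average was highest for the library's own number in 1 of 16 libraries.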
